A study of Drosophila melanogaster with 3 samples.

How the data were processed

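The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Drosophila melanogaster embryos that carry a transgene for eyegone (eyg), a Pax-family transcription factor, fused to green fluorescent protein (GFP). Chromatin of whole embryos of mixed sex, 0 to 24 h old, was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. There are 3 biological replicates of 1 group and no second condition, so no difference between groups was tested. The control library named in the labels was not used here.

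Per the labels and the listings deposited with each library, the authors called regions in each replicate against a control (lists of peaks and background meant as input to the next step), called regions again on the pool of the 3 replicates, and derived an optimal list by the irreproducible discovery rate (IDR), which compares ranks of calls between replicates. Every list was deposited on the builds dm3 and dm6. The aligner, the peak caller and their versions are not given in the sources used here. For each region the deposited lists give a signal value, whose scale is not stated, a −log10 q-value as the authors' caller gave it, and the offset of the summit. The column for scores held 0 and the column for p-values held -1 in every list, so neither was used. The signal is the authors' own value and was used to describe, rank or filter regions and to compare medians within a list, and to correlate replicate lists. The files give no read counts, so the depth of each library is unknown. No interval was formed for the pooled signal of a single region, although the 3 replicate lists each give a signal for most optimal peaks. Intervals on shares of genes or peaks cover counting error only.

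All analyses used the dm6 lists. The dm3 lists were described beside them, with no conversion of coordinates. Gene models were those of Ensembl release 115 on the assembly annotated as BDGP release 6.54, without transposable elements, and sequence came from the RefSeq copy of the same assembly. All dm6 regions lay within the 6 chromosome arms used (2L, 2R, 3L, 3R, 4 and X). Coordinates are 1-based. A site means an optimal peak, and a gene carries a site when a summit lies within 1 kb of one of its annotated transcription start sites (TSSs).

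Replicates were compared by the share of optimal peaks whose summit lies inside a call of each replicate, beside 100 random placements of the same intervals on the same arm. They were also compared by the share of the N highest calls of 1 replicate found among the N highest of another, N being the number of optimal peaks, and by Spearman's rank correlation of signal across optimal peaks. Peaks are not independent replicates, so no p is given for this correlation. The share of summits near a TSS was compared with 1000 random placements within arms (two-sided permutation test, whose smallest possible p is 0.002) and with pooled candidates outside the optimal list (two-sided Fisher's exact test). Signal near and away from TSSs was compared by a two-sided permutation test of the difference in medians with 100000 resamples. Arms were tested with two-sided exact binomial tests against their share of length. Location classes of summits, which were added after the data were examined, were tested in the same way against their share of bases, with overlapping annotations assigned in the order coding exon, 5′ UTR, 3′ UTR, non-coding exon, intron. A total of 22 gene lists were tested with Fisher's exact test against all other protein-coding genes. A total of 17 motifs were tested with an exact McNemar test of presence within 100 bp of the summit against flanks of the same total length centred 500 bp away. Each family was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The list members, motifs, tests and alternatives were fixed before the data were examined.

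The named genes followed a rule fixed at the same time. It takes eyg and its paralog toe, the 20 optimal peaks of highest signal with the gene of the nearest protein-coding TSS, up to 4 members of each list with a site in order of signal, members without a site in lists of fewer than 12 genes, and the 5 highest calls of each replicate that overlap no optimal peak. Some of the genes this rule selects are not reported here. All 561 list entries matched an annotated protein-coding gene. Of these, 6 were older symbols, 4 matched through the synonyms of the RefSeq gene table (h to hry, dof to stumps, tdf to apt, Hsp67Bb to CG4456) and 2 by hand (Dl to Delta, dys to dysf).

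The alternatives covered the overlap that counts, list lengths, the build, the distance to a TSS, the position used, stricter signal thresholds, the assignment of peaks to genes, the background of the list tests, the window and control of the motif tests, and leaving out each replicate. The optimal list could not be remade without a replicate. For location, lists and motifs, leaving out a replicate therefore means keeping only optimal peaks found among the N highest calls of both other replicates. Another 5 alternatives were chosen after seeing the data, namely pooled candidates at a −log10 q of at least 2, the 2 settings restricted to peaks near a single gene, motifs on chromosomes 2 and 3 alone, and motifs at peaks within 1 kb of a TSS.

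The statistics were tested on simulated data. A list of 86 genes with sites added to 60% of its members was called in 50 of 50 simulations over 13945 genes, and 3 of 1050 unchanged lists were called. Shorter lists were not given added sites, so how often an excess in them would be called is unknown. Sites were drawn for each gene separately, whereas neighbouring genes can share a peak. The rate of false calls for real lists may therefore differ. A motif written into 4% of 2537 windows was called in 10 of 10 simulations, and 0 of 160 tests of other motifs were called. Those windows lay at random positions, whereas 67.2% of the optimal summits lay within 1 kb of a TSS. The simulation therefore does not give the rate of false calls at real summits. An arm drawn at 0.75 times its share of 2537 peaks was called in 199 of 200 simulations, and some arm was called in 10 of 200 simulations without a change. Random positions fell past the threshold of the location test in 1 of 20 draws. A shift in median signal of 10% was called in the 1 simulation made, and 0 of 20 simulations without a shift were. These p-values concern only these peaks and libraries. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.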

Results

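Binding of GFP-tagged eyg was mapped by ChIP-seq in whole Drosophila embryos of 0 to 24 h. The tag was on eyg, which encodes a Pax-family factor with a truncated paired domain and a homeodomain and is known for its part in eye and salivary duct development. The 3 biological replicates form 1 group, and the question the design addresses is where in the genome the tagged protein was found. The optimal list held 2537 regions on dm6, covering 1013 kb. Their signal ran from 108.3 to 2151 with a median of 156.2, and 91.2% of them had the full width of 424 bp. The 223 narrower regions had a median signal of 478.5, against 150.4 for those of full width. Candidate lists were longer, with 23721 regions in the pool and 30000, 30000 and 24609 in replicates 1, 2 and 3. The optimal list was made of the 2537 pooled candidates of highest signal. Because 2 lists have exactly 30000 regions, the number of candidates was not used to rank the replicates, whose read depth is unknown.

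The strongest sites lay at promoters and in introns. The highest signal, 2151, was at X:2703699-2704076, 32 bp from the TSS of Ugalt, a UDP-galactose transporter. It was followed by an intronic peak 1399 bp from the nearest TSS of cbt at 2L:480874-481274 (signal 1975) and a peak 101 bp from CG14100 at 3L:19590443-19590801 (1782). Next came the peaks nearest px at 2R:22514122-22514481 (1508), CG11050 at 2L:6612517-6612902 (1495) and SCaMC, a mitochondrial carrier gene, at 3L:12406986-12407285 (1480). The nearest TSSs of CG11050 and SCaMC lay 1023 and 1501 bp away. Signals of the peaks ranked 7 to 20 ran from 1382 down to 960.2. Their nearest protein-coding TSSs were those of PNPase, mRpL41, Lk6, Art3, Chro, ph-p, hll, CG1888, CG4004, CG9663, CG31145, CG32772, CenG1A and Shc. Among these genes, Chro encodes a chromodomain protein of interbands and ph-p a Polycomb-group protein. The TSSs of hll, CG4004 and CG32772 lay 2921, 5087 and 1261 bp away. The Ugalt, Art3 and CenG1A peaks also lay within 1 kb of a TSS of eIF2Bbeta, mRpS10 and mRpS23, in that order. Of the 20 peaks, 14 lay within 1 kb of a protein-coding TSS, and 8 summits were in introns, 7 between genes, 3 in 5′ UTRs and 2 in non-coding exons. The peak at Ugalt was the highest call in each replicate list, with signals of 562.2, 770.6 and 825.0 in replicates 1, 2 and 3.

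The eyg gene itself carried a site. A peak at 3L:12468012-12468435 had its summit 203 bp upstream of the eyg TSS (signal 177.0, rank 1020), and a weaker one lay 10536 bp from that TSS, beyond the 3′ end of the gene at 3L:12457273-12457696 (139.3). The paralog toe, at 3L:12422510-12432668, had no site within 1 kb of a TSS. The optimal peak closest to the toe TSS was 23452 bp away, in an intron of SCaMC. From 30 kb before toe to 30 kb after eyg there were 9 optimal peaks, where the mean density over the 6 arms gives 2.00. Only the peaks 203 and 10536 bp from the eyg TSS had eyg as the nearest protein-coding gene. The others were nearest SCaMC, CG33725, CG10663 or CG10660. All of these but the strongest SCaMC peak, at 1501 bp, lay 3 to 570 bp from that TSS. The window also held 32 further candidates below the threshold.

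**Figure D1:**
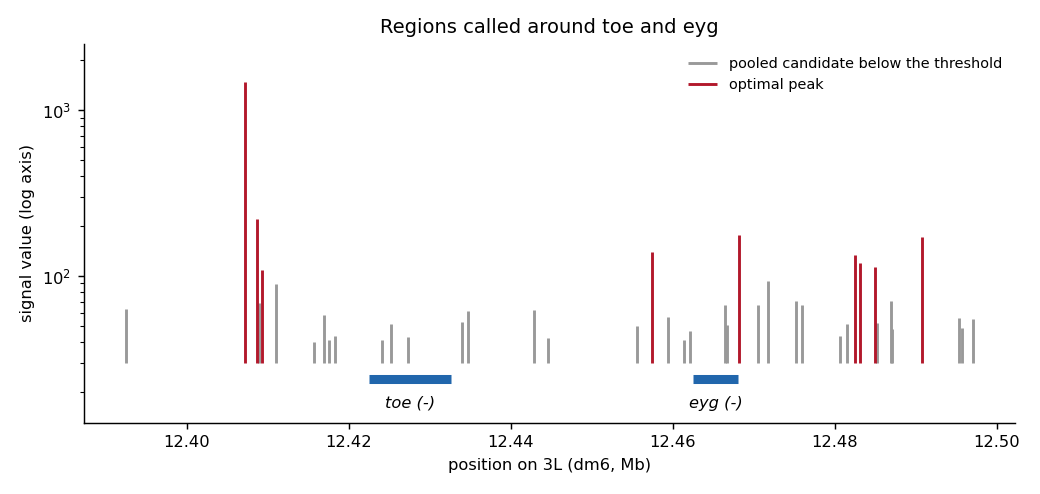
Regions called in the pooled list from 30 kb before toe to 30 kb after eyg, with the summit position on 3L (dm6, Mb) on the x axis and the authors' signal value on a log y axis. Red lines are the 9 optimal peaks, grey lines the 32 candidates below the threshold, and blue bars the 2 genes, both on the minus strand; the highest line is the SCaMC peak at 1480.

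Sites were found again in the 3 replicates, with less agreement on their order. A call of replicate 1, 2 and 3 held 98.9%, 99.6% and 99.7% of the optimal summits (mean 99.4% ± 0.480, SD, n = 3), where random placements gave 8.85%, 8.89% and 7.28%. The optimal list was derived from the same libraries, so this recovery is not independent. Per the labels the replicate lists hold background regions beside peaks, and 2050, 2927 and 2800 of their regions had a −log10 q of at least 2. Among the 2537 highest calls of each replicate, the recovery was 77.0%, 82.1% and 83.4%. Of the optimal peaks, 57.9% were among the 2537 highest calls of all 3 replicates, 27.6% of 2, 13.8% of 1 and 0.788% of none. Between pairs of replicates, 67.4% (1 and 2), 67.2% (1 and 3) and 71.4% (2 and 3) of these calls were shared, a mean of 68.7% ± 2.39 (SD, n = 3 pairs). Spearman's rank correlation of signal across optimal peaks was 0.66, 0.66 and 0.70 for the same pairs.

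**Figure D2:**
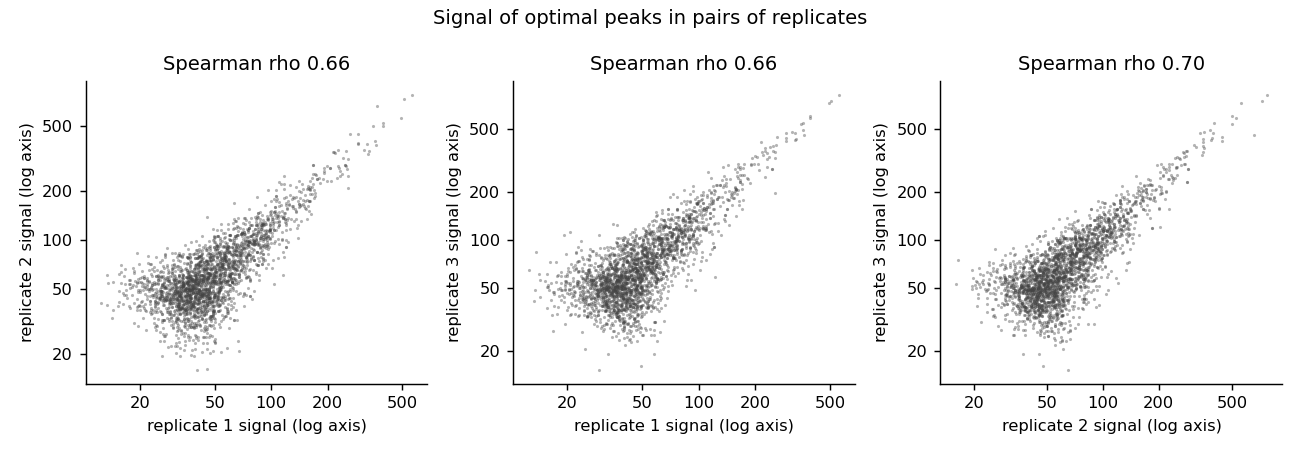
Signal of the optimal peaks in pairs of replicates, one point per peak called in both, on log axes in the units of each list. Spearman's correlation was 0.66, 0.66 and 0.70 over 2528, 2527 and 2534 peaks; strong peaks lie close to a line and weak ones scatter.

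Calls seen outside the optimal list were at pic, CG12290 and brat in replicate 1, with signals of 52.3 to 58.1. In replicate 2 the nearest protein-coding TSSs were those of shn, mRpL2, Cyp28d2, yuri and NFAT, with signals from 59.5 to 66.2. Those of shn, Cyp28d2 and NFAT lay 1684, 10357 and 1353 bp away. In replicate 3 the nearest were those of prage, Hrb27C, Hs6st, aop and Paip2. The call at prage, at X:1830657-1830853, stood apart with a signal of 181.0, rank 125 in replicate 3. It overlapped no pooled candidate, though regions overlapping it had signals of 90.8 in replicate 1 and 124.9 in replicate 2, and its recorded summit is the base after its end. The other 12 calls named here ranked between 720 and 1230 in their own lists, and each overlapped a pooled candidate below the optimal threshold, with a pooled signal of at most 108.0.

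Sites were concentrated at promoters. Of 2537 summits, 1705 (67.2%, 95% Wilson interval 65.4% to 69.0%) lay within 1 kb of a TSS, and the median distance was 320 bp. Random positions gave 23.7% (range 21.1% to 26.4%, permutation p = 0.002, the smallest that 1000 placements can give). Pooled candidates outside the optimal list lay near a TSS in 43.7% of 21184 cases (Fisher's exact p = 8.08e-112). The share of summits in 5′ UTRs was 12.9%, 4.21 times the share of bases (adjusted p = 2.68e-103, exact binomial test). Coding exons held 0.828% of summits although they make up 17.1% of bases (exact adjusted p = 1.82e-168), and 3′ UTRs held 1.30% against 4.92% (1.14e-22). Introns held 46.0% of summits against 42.6% of bases, and regions between genes 35.9% against 30.6%. The median signal was 159.2 near TSSs and 151.2 elsewhere (permutation p = 0.0138), and with 500 bp as the limit the difference was 4.15 with p = 0.155.

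**Figure D3:**
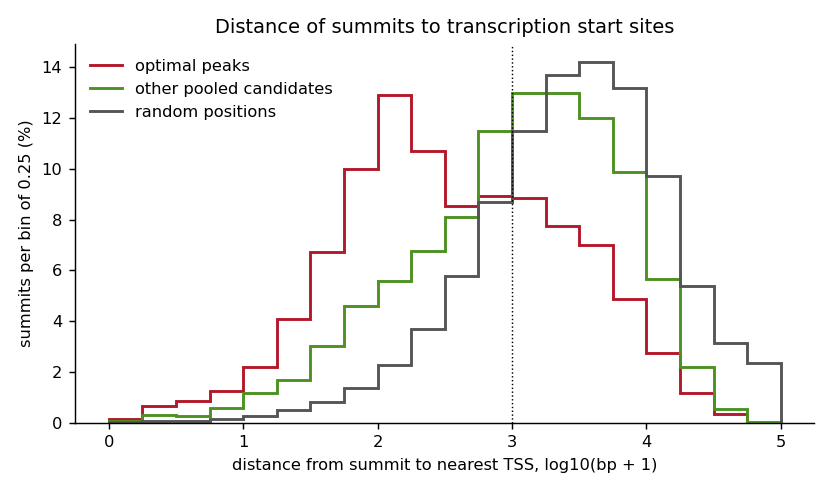
Distance from each summit to the nearest TSS, as log10(bp + 1), for 2537 optimal peaks, 21184 other pooled candidates and random positions on the same arms; the y axis is the percent of summits in each bin and the dotted line marks 1 kb. Optimal peaks are most frequent in the bin from 2 to 2.25, with 12.9% of summits against 2.29% of random positions.

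Chromosome arms differed little. Arm 4, a small and largely heterochromatic chromosome, held 11 peaks, 0.434% against an expected 1.01% by length (adjusted p = 0.0116, exact binomial test over 6 arms). The other arms lay between 0.964 and 1.05 times their expected share, none past the threshold. The result for arm 4 was not past the threshold when the expectation was its share of protein-coding genes (0.756 times, exact adjusted p = 0.613).

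Genes of the cytoplasmic ribosome carried sites far more often than other genes. Of 13945 protein-coding genes, 2049 (14.7%) had a site within 1 kb of a TSS. In the ribosomal list 66 of 86 genes did (76.7% against 14.3% of the others, adjusted p = 8.40e-37, Fisher's exact test over 22 lists). The strongest were RpS27 at 3R:25247379 onward (signal 820.5, summit in the 5′ UTR 2 bp from a TSS), RpL7 (534.3), RpL14 (522.6) and RpL23A (521.0). In 58 of the 66 peaks the nearest protein-coding TSS was that of a ribosomal gene. Many of these genes have close neighbours. With only peaks that had a single gene within 1 kb, 8 of 86 carried one (9.30% against 5.50%, exact adjusted p = 0.539), and among genes with no other TSS within 1 kb 7 of 20 did (35.0% against 9.08%, adjusted p = 0.0134); both settings were chosen after seeing the data. The proteasome list had sites at 5 of 32 genes (15.6%, exact adjusted p = 1), including Rpn5 (216.4), Rpn3 (165.2), Rpn2 (162.6) and Rpn6 (160.8).

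Genes for chemosensory receptors, which serve smell and taste, carried few sites, 3 of 179 (1.68% against 14.9%, adjusted p = 3.84e-08, Fisher's exact test). The 3 were Ir60e (133.4), Gr64a (126.5) and Or88a (112.1). Among genes that had a pooled candidate near a TSS the list was not past the threshold (0.396 times, exact adjusted p = 0.505). None of 13 chorion and vitelline membrane genes had a site, which allows a share of up to 24.7% (95% exact limit, exact adjusted p = 0.769).

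In the EGF receptor pathway 6 of 12 genes had a site (3.41 times the share of the other genes, adjusted p = 0.0305, Fisher's exact test). Among them were the ligands spi (signal 422.8, 2L:19575603 onward, intron) and Krn (205.8), the repressor aop (170.7) and the antagonist sty (164.2). This call ended against gene sets matched on gene span (permutation test, adjusted p = 0.366) and without each replicate in turn, with ratios of 3.05, 3.25 and 2.47 and adjusted p of 0.252, 0.206 and 0.630 without replicates 1, 2 and 3. It also ended among genes that had a pooled candidate (1.92 times, exact adjusted p = 0.505) and in the 1268 peaks of highest signal (4.09 times, 0.0943). It held by nearest TSS (4.81 times, exact adjusted p = 0.000295) and by gene body (3.14 times, 0.00198).

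No list of eye, Pax or patterning genes passed the threshold. Of the retinal determination genes, 3 of 15 had a site (1.36 times the share of the others, exact adjusted p = 0.949), at eyg (177.0), dac (146.6) and ey (113.0). In the Pax family it was 3 of 10 (exact adjusted p = 0.756), at eyg, Poxm (117.3) and ey, and none at Poxn, gsb, gsb-n, prd, sv, toe or toy. None of the 8 Hox genes (Abd-B, Antp, Dfd, Scr, Ubx, abd-A, lab and pb) and none of 22 segmentation genes had a site, which allows shares of up to 36.9% and 15.4% (95% exact limits, exact adjusted p = 1 and 0.349). The salivary gland list had 3 of 18, fkh (386.3), ps (197.3) and eyg, and the notum list 1 of 13, ush (178.3), with exact adjusted p = 1 for both.

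No other signalling list passed. The Wnt list had 4 of 17 (sgg at 377.8, Axn at 136.7, arr at 136.5 and nkd at 120.6; exact adjusted p = 0.769) and the Dpp list 4 of 15 (shn at 399.2, Mad at 356.0, brk at 192.2 and bi at 119.5; adjusted p = 0.769). When a summit anywhere in the gene body or within 2 kb counted, the Dpp list passed with 9 of 15 (2.51 times the others, exact adjusted p = 0.0165). Such a count gives long genes more room, and it was not compared with sets matched on gene span. The Notch list had 2 of 16, E(spl)m3-HLH (155.7) and N (112.0). The JAK/STAT list had 1 of 9, Stat92E (196.5), and none at Ptp61F, Socs36E, dome, et, hop, upd1, upd2 or upd3. The Hedgehog list had 1 of 8, rdx (322.4), and none at Su(fu), ci, cos, fu, hh, ptc or smo. All 3 had an exact adjusted p of 1.

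No list of markers of other tissues passed, and these lists are small. Neural genes had 1 of 21, elav (335.6), with exact adjusted p = 0.769, and muscle genes 2 of 18, sls (191.9) and Mef2 (108.4). Tracheal genes had 2 of 10, bnl (135.6) and apt (116.5), and none at btl, dysf, esg, kni, rib, stumps, trh or vvl. Gut and fat body genes had 2 of 11, fkh and Adh (108.4), and none at Fbp1, GATAe, Lsp1alpha, Lsp1beta, Lsp1gamma, Lsp2, byn, cad or srp. Hemocyte genes had 1 of 10, ush, and none at Col4a1, Hml, NimC1, Pxn, crq, gcm, lz, srp or vkg. Heat shock genes had 4 of 18, Hsp83 (530.2), Hsp27 (366.9), Hsp26 (193.2) and Hsp68 (158.1), with exact adjusted p = 0.769. The muscle, tracheal, gut and hemocyte lists had an exact adjusted p of 1.

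**Figure D4:**
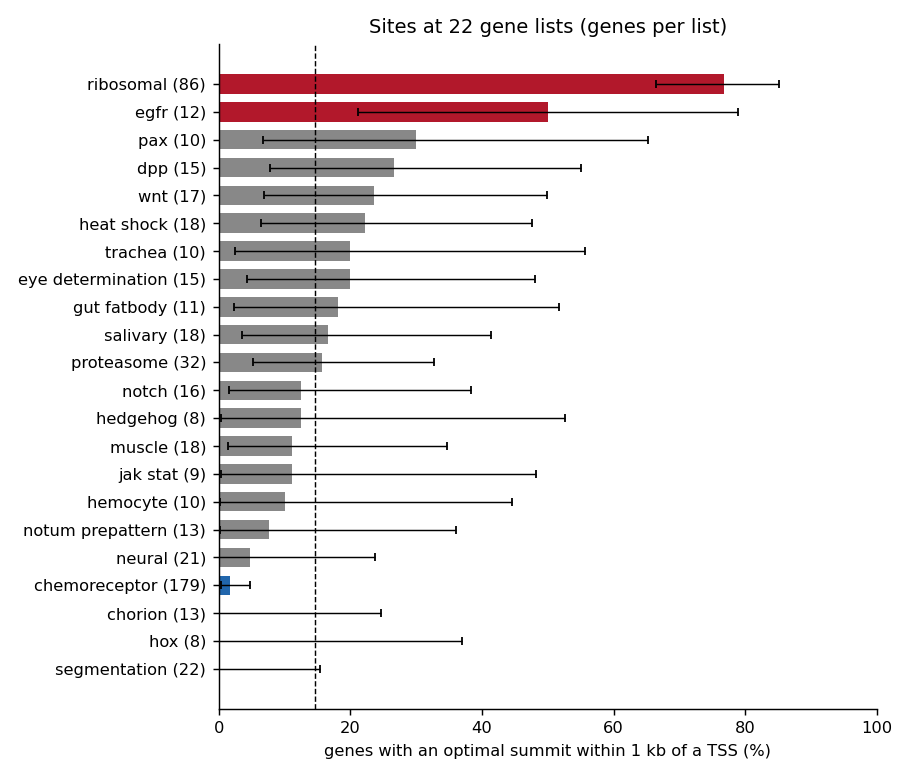
Percent of genes with an optimal summit within 1 kb of a TSS in 22 gene lists, with the number of genes in parentheses and 95% exact binomial intervals as error bars. Red lists lay above and blue below the other genes at an exact adjusted p under 0.05, grey lists did not pass, and the dashed line is the share of all protein-coding genes, 14.7%.

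Of the 17 motifs, the 4 that passed with more sites at summits were core promoter elements. The DNA replication-related element TATCGATA, the site of Dref, was found within 100 bp of 4.49% of summits and in 0.946% of flanks (4.75 times, adjusted p = 3.09e-14, exact McNemar test over 17 motifs). Motif 1, GGTCACACT, the site of M1BP, was at 1.97% and 0.512% (3.85 times, exact adjusted p = 1.28e-05), the E box CAGCTGTT at 4.73% and 2.09% (2.26 times, 1.62e-06) and core promoter motif 6 at 4.18% and 2.56% (1.63 times, 0.00724). The GGTCACACT call ended without replicate 1 (2.36 times, exact adjusted p = 0.0683) and without replicate 2 (2.33 times, 0.0564), and in the 1268 peaks of highest signal (1.89 times, 0.358), where CAGCTGTT also did not pass (1.73 times, 0.0516). Motif 6 did not pass with a window of 50 bp (1.5 times, exact adjusted p = 0.226). The repeat CACACACA was less frequent at summits, 4.77% against 8.04% (0.593 times, exact adjusted p = 8.79e-06), but not against pooled candidates outside the optimal list (0.866 times, 0.214). Among 832 peaks over 1 kb from a TSS no motif passed, and TATCGATA was at 0.240% of summits and 0.361% of flanks (0.667 times, exact adjusted p = 1).

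Sequences of homeodomain and paired-domain proteins did not pass over all peaks. TAATTA, the homeodomain core, was at 13.8% of summits and 12.7% of flanks (exact adjusted p = 0.566), with 13.9% and 11.1% at peaks near TSSs (1.25 times, adjusted p = 0.0448, a test added after seeing the data), and the palindromes TAATNNATTA and TAATNNNATTA had ratios of 1.19 and 1.18 (adjusted p = 0.667 for both). A pattern after part of the Pax6 splice-form site was at 2.01% and 2.09% (exact adjusted p = 0.976), and the paired-domain pattern was at 0 of 2537 summits, which allows a share of up to 0.118% at 3 counts (adjusted p = 1). The GAGA element, CAGGTAG of Zelda, the Su(Hw), AP-1, GATA, ETS and Stat92E sites also did not pass. Against pooled candidates outside the optimal list, TAATTA passed (1.28 times, adjusted p = 5.02e-05), as did the GAGA element (1.41 times, 0.000765), TAATNNATTA (1.51 times, 0.0312) and the ETS site (2.68 times, 0.0312), by Fisher's exact test. The ETS site was at only 9 of the 2537 summits. Optimal peaks lay within 1 kb of a TSS in 67.2% of cases and these candidates in 43.7%, and the comparison did not adjust for that.

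**Figure D5:**
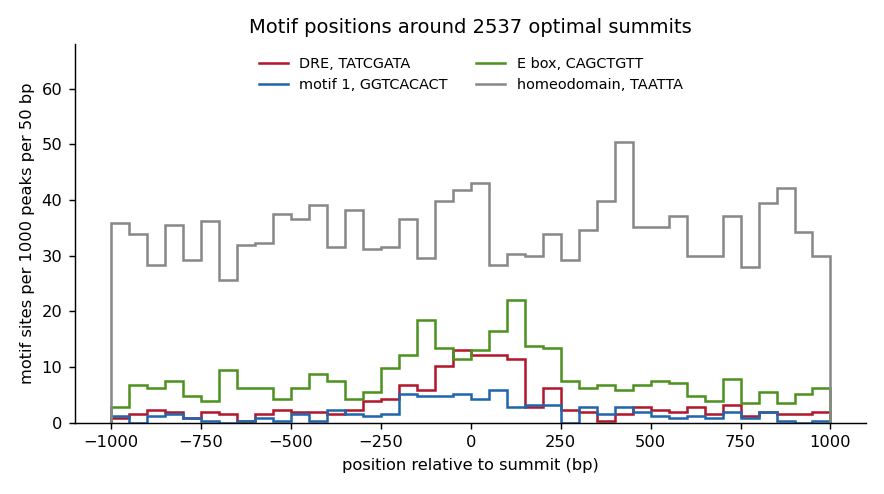
Motif sites per 1000 peaks in bins of 50 bp, from 1000 bp before to 1000 bp after 2537 optimal summits, for TATCGATA, GGTCACACT, CAGCTGTT and TAATTA on either strand. The first 3 are more frequent near the summit, while TAATTA does not pass (exact adjusted p = 0.566).

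The lists on the older build dm3 held 2459 optimal and 20751 pooled regions, against 2537 and 23721 on dm6. By arm, the optimal peaks on dm3 and dm6 numbered 456 and 470 on 2L, 472 and 488 on 2R, 503 and 522 on 3L, 599 and 616 on 3R, 11 and 11 on 4, and 418 and 430 on X. The highest signal was 2151 on both builds and the median 158.3 on dm3 and 156.2 on dm6. On dm3, 35 pooled candidates lay outside these arms. No test was made between builds, since both were made from the same libraries.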

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

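The settings restricted to peaks near 1 gene, the motif tests on chromosomes 2 and 3 and at peaks within 1 kb of a TSS, and the count of pooled candidates at a −log10 q of 2 or more were chosen after seeing the data. No paired analysis was possible because there is 1 group. Of 57 alternatives of the main results, 42 kept the side of the threshold, stayed within the spread or, for lists and motifs, gave a similar number of calls, which were not always the same calls. Among the 42 was every alternative of the share near TSSs (56.4% to 78.0%). The recovery of optimal peaks was 95.5% with 50% reciprocal overlap and 80.8% among the N highest calls. The shared top calls were 74.5% with 0.5 times N, 60.4% with 2 times N, and 67.2% to 71.4% when 1 replicate was left out. The mean Pearson r of log2 signal was 0.77, and Spearman's correlation ran from 0.66 to 0.70 without 1 replicate. The difference in signal near TSSs was 4.15 at 500 bp, no longer past the threshold. The 50% of peaks with the highest signal number 1268 by construction. In this set 0 arms, 3 motifs and 2 lists passed, with arm 4 still at 0.470 times its share (exact adjusted p = 0.390), and 0 arms passed with protein-coding genes as expectation. With only genes that had a candidate 1 list passed, the ribosomal one. Of 17 motifs, 8 passed against candidates outside the optimal list and 0 over 1 kb from a TSS. The cause was not tested for any of these. The EGF receptor list was lost with span-matched sets (2.21 times), with genes that had a candidate (1.92) and without each replicate (2.47 to 3.25), and in the peaks of highest signal although the ratio was 4.09 there. The chemoreceptor list was lost with genes that had a candidate, and the ribosomal list with peaks near 1 gene. Motif 6 was lost with a window of 50 bp (1.5 times, exact adjusted p = 0.226), and CACACACA against candidates outside the optimal list (0.866 times, 0.214). In the peaks of highest signal GGTCACACT (1.89 times, exact adjusted p = 0.358) and CAGCTGTT (1.73 times, 0.0516) were lost. The GGTCACACT call was also lost without replicate 1 (2.36 times, exact adjusted p = 0.0683) and without replicate 2 (2.33 times, 0.0564). Of the values for single lists, motifs and arms, 75 lay on the other side of 1 and past the threshold on neither side, and 3 others changed side. These were TATCGATA over 1 kb from a TSS (0.667) and the GAGA element, which passed with a window of 200 bp (1.21) and against other candidates (1.41). The ratios of the rest follow. In the peaks of highest signal they were 0.964 for arm 3R, 1.00 for X, 0.816 for retinal determination, 1.36 for JAK/STAT, 0.720 for Wnt, 1.53 for Hedgehog, 0 for trachea and 1.22 for hemocytes. By protein-coding genes they were 0.972 for 2L, 0.941 for 2R, 1.05 for 3L, 0.990 for 3R and 1.08 for X. By gene body they were 1.39 for JAK/STAT, 1.31 for Notch, 1.05 for Hedgehog and 1.16 for muscle. By nearest TSS they were 2.40 for JAK/STAT, 1.35 for Notch, 1.80 for Hedgehog, 1.11 for notum, 1.6 for muscle, 1.44 for hemocytes and 0.899 for proteasome. With span-matched sets they were 0.904 for retinal determination, 0.791 for salivary gland, 0.915 for trachea and 0.981 for gut and fat body. With genes that had a candidate they were 0.852 for trachea and 0.767 for proteasome. With peaks near 1 gene they were 2.01 for JAK/STAT, 1.13 for Notch, 2.27 for Hedgehog, 1.39 for notum, 1.01 for muscle, 1.81 for hemocytes and 0 for gut and proteasome. With lone genes as background they were 1.82 for JAK/STAT, 3.65 for Hedgehog, 1.09 for hemocytes and 0 for gut and proteasome. Without 1 replicate the whole range, which for the first pair of lists spans 1, was 0.648 to 1.83 for retinal determination, 0.972 to 1.83 for Pax, 1.02 to 1.1 for JAK/STAT, 1.14 to 1.23 for Hedgehog, 0 to 0.986 for trachea and 0.831 to 0.896 for gut. Within 50 bp they were 1.04 for the Pax6 pattern and 1.05 for Stat92E, and within 200 bp 0.907 for TAATNNATTA and 1.06 for AP-1. Against other candidates they were 1.08 for the Pax6 pattern, 0.928 for Su(Hw), 1.14 for AP-1, 1.17 for GATA and 1.04 for Stat92E. Over 1 kb from a TSS they were 0.850 for TAATTA and 1.57 for Zelda. Within 1 kb of a TSS they were 1.21 for the Pax6 pattern and 1.02 for GAGA, and TAATTA passed there (1.25). On chromosomes 2 and 3 they were 1.1 for the Pax6 pattern, 1.02 for GAGA and 1.02 for AP-1. Read depth, which is unknown, limits what the signal of single weak regions can show.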

Other observations

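The gene lists of the next paragraph, the search over words of 7 bases, and the tests of the base composition of words, of CACTGAG at ribosomal protein genes and of the eyg and toe locus were chosen after the results had been seen; the tests of CACTGAG at ribosomal genes and of developmental windows replaced earlier versions that had not decided.

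Another 10 gene lists were tested in the same way, with Fisher's exact test adjusted over these lists. Abundant transcripts other than ribosomal proteins carried a site at 18 of 40 genes (45.0% against 14.6% of the other genes, exact adjusted p = 4.18e-05), with Hsp83 (signal 530.2), Gapdh2 (525.6), eEF1gamma (407.1) and Act5C (287.6) the strongest. Insulator and architectural proteins, which organise chromatin, did so at 7 of 16 genes (43.8%, exact adjusted p = 0.0124). Among them were Chro (1146), Dref (314.3), Cp190 (237.3) and Trl (207.2). The Dref peak was also the one counted for RpL13, and these 10 lists were not tested with peaks near a single gene. Translation factors had 14 of 51 (27.5%, exact adjusted p = 0.0320), which was 0.0590 against sets matched on gene span. Cuticle proteins of the CPR family had 1 of 92 (1.09%, exact adjusted p = 5.48e-05), at Cpr73D (123.6), and cytochrome P450 genes 2 of 75 (2.67%, adjusted p = 0.00491), Cyp6u1 (144.9) and Cyp310a1 (129.0). Mitochondrial ribosomal proteins had 13 of 73 (17.8%, exact adjusted p = 0.495, and 0.0405 against span-matched sets), although mRpL41 (1308), mRpS10 (1147) and mRpS23 (974.2) stood at 3 of the 20 strongest peaks. NADH dehydrogenase and ATP synthase genes (10 of 55), Rab GTPases (6 of 23), splicing proteins (5 of 17) and aminoacyl-tRNA synthetases (5 of 33) did not pass.

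A search over 8192 words of 7 bases, each taken with its reverse complement, found 1143 past an exact adjusted p of 0.05, of which 505 were more frequent at summits than in flanks and the others less frequent. Higher ranks by p went to words such as CTATCGA (4.34 times), CAGTGTA (4.41 times) and ACACTGA (3.29 times), but also to words rich in A and T that were more frequent, such as TTTAAAA (1.84 times), and to words rich in C that were less frequent, such as CTCCTCC (0.214 times).

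Peaks at ribosomal protein genes, taking the highest for each gene, also had a higher median signal than other peaks near TSSs. The medians were 223.0 over 66 peaks and 158.0 over 1639 (permutation p = 1e-04, the smallest that 10000 resamples can give). The 1639 peaks were not limited to the highest of each gene, so part of the difference may come from that choice. If any highly transcribed promoter were called alike, abundant genes outside the ribosome would carry sites as often. Of the listed abundant genes 45.0% did, against 76.7% of ribosomal protein genes (Fisher's exact p = 0.000975). The lists were not matched on expression, and the abundant genes were not tested with peaks near a single gene. The lower share therefore does not decide whether high transcription is the cause. Of 290 tRNA genes, which RNA polymerase III transcribes, 6.55% had a site against 14.7% of protein-coding genes, so tRNA genes were not called more often. How well reads map to tRNA genes was not examined. The shares therefore do not settle whether RNA polymerase III loci in general are called alike. The word CACTGAG was at 0 of the 66 peaks, with an upper limit of 5.44%, against 3.42% of other peaks near TSSs. Fisher's exact test left that open (p = 0.168). The limit, applied afterwards, shows that few of these peaks held the exact word. Because the word was at 4.89% of all summits, a rule that required it in the majority of these peaks could hardly have been met. Sequences related to the word were not searched, so a role for them stays open. In a comparison outside the planned tests, TATCGATA was at 24.2% of the 66 peaks and 5.86% of the others near TSSs (Fisher's exact adjusted p = 3.81e-05). GGTCACACT was at 10.6% and 2.56%, and motif 6 at 13.6% and 4.09% (exact adjusted p = 0.0126 for both). None of the other motifs passed, and whether these elements bring the sites was not tested. A graded effect of transcription on the precipitate stays open, since abundant genes still lay above the background share and no expression level or untagged control was analysed here.

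The word CACTGAG ranked 22 and was picked because its reverse complement CTCAGTG lies in the consensus of the alternatively spliced paired domain of Pax6. It was at the summits of 124 peaks and in the flanks of 38 (3.26 times, exact McNemar adjusted p = 1.02e-09). In peaks over 1 kb from a TSS it was at 8.17% and 1.20%, and near TSSs at 3.28% and 1.64%. Without peaks holding GGTCACACT, the site of M1BP, the ratio was 3.27. Only 50 of 2537 peaks held that site, and 121 summits and 37 flanks kept the word, so the ratio could hardly fall. Overlap with looser forms of the M1BP site therefore stays open. Base composition was examined with 629 other words of the same composition. Their median ratio was 0.868, so they were mostly less frequent at summits than in flanks. This argues against base composition alone as the cause. Of these words, 0.159% reached the ratio of CACTGAG. That share decides nothing, since a word picked from the scan is bound to lie high among words of its composition. The word may be a site of the tagged protein, as a hypothesis. However, words sharing CACTG or its complement without that extension ranked higher (CAGTGTA at 4.41 times, ACAGTGG at 2.80). The planned Pax6 pattern did not pass (0.962), but it follows only part of the Pax6 site and does not contain the word. It therefore does not test the word. Of the 634 peaks with the highest signal 3.94% held CACTGAG and of the 634 with the lowest 5.05% (Fisher's exact p = 0.416), which leaves the hypothesis open.

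The window from 30 kb before toe to 30 kb after eyg held 9 optimal peaks. Of these, 3 were at SCaMC and 4 beyond the eyg promoter peak, nearest the TSSs of CG33725, CG10663 and CG10660. As many optimal peaks were found in 1.55% of 13328 windows of that size. Extra copies of the tagged locus could raise all calls there; 8.98% of windows had as many candidates below the threshold (32, with a median of 17), which decides neither way. A cluster as found at other developmental genes could also raise the number of optimal peaks. Of 208 windows centred on genes of the 17 developmental lists, 9 had as many optimal peaks (4.33%, exact upper limit 8.05%). Windows of neighbouring genes can overlap, so that limit, which treats them as independent, may be too low. Both explanations stay open.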
